A study of Mus musculus with 12 samples.

How the data were processed

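ATAC-seq measures open chromatin: a transposase cuts accessible DNA and adds sequencing adapters in the same step, so that places with many fragments mark accessible regions. Splenic natural killer (NK) cells of mice were profiled, with the same number of cells per library and a commercial ATAC-seq kit, per the labels' protocols. Replicate numbers and groups were taken from the sample titles. The groups were wild-type control, wild-type stimulated with IL-12/18, knockout control and knockout stimulated with IL-12/18, with 3 libraries each.

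The authors processed the reads and deposited 1 peak list per library. The tools named, per the submitters' processing notes, were FastQC 0.11.9, cutadapt 4.1, Bowtie2 2.3.4.1, SAMtools 1.15.1, deepTools 3.4.2 and MACS2 2.1.1.20160309, and the genome build was mm10. The notes as used here give no role, order or settings for these tools, and whether reads were shifted for the transposase's cut is not given in the sources used here. Peaks were called separately in each library, since each deposited list carries its own sample's name and its own peaks. The deposited fold is a ratio, the peak's pileup over the background of its own library, and the deposited −log10 p and −log10 q values also belong to the single peak within its own library. These values are the authors' and were used only to rank and filter peaks within a list, never to compare a peak's height between libraries. The lists still held peaks on the mitochondrial chromosome and a chromosome 2 peak with deposited folds of 4805 to 7138 that resembles satellite DNA. Only chromosomes 1 to 19, X and Y were used.

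Several summits called within 1 interval were taken as 1 distinct interval with the values of its strongest summit. Total read depth is unknown, since peak lists do not give it. A relative depth was read from the lists: in each library 100% of the deposited folds under 5 were whole multiples of a library-specific step, within 0.02 of a whole number of steps. If the caller adds 1 to pileup and background, that step implies a background coverage of 1/step − 1 fragments per base. That assumption was not checked against reads.

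Because the lists had very different lengths, every library was reduced to its 35110 strongest distinct intervals by deposited −log10 q, the length of the shortest list. The 12 reduced lists were merged wherever intervals shared at least 1 bp, and a region counted as called in a library when an interval of that library's reduced list overlapped it. Regions called in at least 2 libraries were kept. A region that was not called in a library can still hold a weaker deposited peak there. A region was gained in a comparison when called in 3 of 3 libraries of the first group and 0 of 3 of the second, and lost in the opposite case. With 3 libraries against 3, an exact permutation test cannot go below p = 0.1, so these counts carry no p-value of their own.

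To test single regions, both genotypes (for the treatment) or both treatments (for the genotype) were combined. The number of libraries with a call was compared by an exact two-sided conditional permutation test with the margins fixed within each stratum. It has 400 rearrangements and a smallest possible p of 0.005. Benjamini-Hochberg adjustment at 0.05 covered the regions whose margins allow a p of 0.05 or less. The test was tried on simulated data over 45082 regions, with each library drawn independently. Unchanged regions were drawn at the real call rates. Changed regions were nearly always called in one group and nearly never in the other, in the same direction in both strata. The recoveries below hold for such near-complete switches and not for smaller differences. With 200 changed regions it called none for either effect. With 2000 changed regions it recovered 53.1% for the treatment and 89.2% for the genotype, and with 4000 it recovered 88.1% and 87.5%, so a small number of genotype regions cannot pass the adjustment whatever their separation.

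Regions were assigned to the nearest protein-coding gene body within 50 kb, ties going to the nearer gene end, with gene positions of assembly GRCm38.p6, the assembly behind mm10. The planned rule was the nearest transcription start site. The gene table used here holds gene starts and ends without strand, exons or sequence, so start sites, exons, introns and untranslated regions are not given, and the planned motif comparisons were not run. "Near a gene end" below means within 1 kb of either end of a gene. Of the 21887 protein-coding genes in the table, 14359 received at least 1 region.

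The 16 gene lists were fixed before the data were examined: cytokines and chemokines, cytotoxic granule, cytokine receptors and JAK-STAT, NF-kB pathway, AP-1 family, NK transcription factors, NK receptors, checkpoint receptors and ligands, homing and maturation, RNA decay with reported Regnase-1 targets, growth and metabolism, markers of B, T, myeloid and erythroid cells, and ubiquitous genes. For each list the called regions assigned to its genes were counted per library and compared by the exact two-sided permutation test within strata (400 rearrangements), with Benjamini-Hochberg adjustment over the 16 lists. Fisher's exact test compared the share of higher or lower regions near list genes with that of all regions tested. A difference between the treatment effects of the genotypes was tested as a difference of differences, with genotype permuted within treatment. The rule for named genes was also fixed beforehand: Zc3h12a, Ifng, Pou2f2 and Nfkbiz always, the first 24 list genes by number of regions that passed the treatment test, up to 16 list genes for the genotype by gained and lost regions (no region passed the genotype test), and the 4 genes of the genome with most regions in each direction.

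To ask whether regions gained in stimulated wild-type cells were already called in unstimulated knockout cells, each wild-type control library was left out in turn, regions called in 3 of 3 stimulated and 0 of the 2 remaining wild-type control libraries were taken, and the share of them called in the left-out library was set beside the share called in each knockout control library. Leaving out the measured library keeps the selection from forcing the wild-type share to 0.

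Intervals on shares of regions are Wilson 95% intervals and cover counting error only, and regions are not independent replicates. The most similar libraries within a group shared a Jaccard index of 0.895, so no library was a copy of another. Alternatives tried were all deposited peaks, 17555 peaks per library, calls that cover at least 50% of the region, windows of 250 bp on either side of summits, autosomes only, rearrangement within replicate numbers, Fisher's exact test without strata, gene bodies with 20 kb flanks, peaks with a deposited −log10 q of at least 5, and leaving out each library. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.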

Results

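Chromatin accessibility was measured by ATAC-seq in NK cells from mouse spleen. NK cells are innate lymphocytes that kill infected and tumour cells and release interferon gamma. The cells were wild type (WT, with a floxed Regnase-1 allele) or lacked Regnase-1 in NK cells (knockout, KO), and were either unstimulated controls or stimulated with IL-12 and IL-18, cytokines that together drive NK cells to make interferon gamma. Regnase-1, the product of Zc3h12a, is an endoribonuclease that degrades messenger RNAs of inflammatory genes. The design asks how the accessible genome of NK cells changes with the loss of Regnase-1, at rest and under stimulation. Each of the 4 groups had 3 libraries. The labels do not say whether the 3 came from separate animals, so the p-values measure the spread between these samples, which may be technical.

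The deposited lists held 48095 ± 5464 distinct peak intervals in WT control cells (SD, n = 3), 58236 ± 4285 in WT stimulated cells, 50910 ± 3432 in KO control cells and 43985 ± 9677 in KO stimulated cells. Single lists ran from 35110 intervals in KO stimulated replicate 1 to 63128 in WT stimulated replicate 3. The stimulated minus control difference in list length was 1608 (exact permutation p = 0.745) and the KO minus WT difference −5718 (exact permutation p = 0.24, within strata, two-sided). Both combine differences of opposite sign. Stimulated minus control was 10141 in WT (exact permutation p = 0.1) and −6925 in KO cells (exact permutation p = 0.4). KO minus WT was 2816 in control (exact permutation p = 0.7) and −14251 in stimulated cells (exact permutation p = 0.1). The difference of differences was −17066 (exact permutation p = 0.07). The background coverage implied by the deposited folds was 1.80 fragments per base in KO stimulated replicate 1 and 2.84 to 4.36 in the other 11 libraries. Across the 12 libraries it went with list length with Pearson's r = 0.618 (permutation p = 0.0461) and Spearman's rho = 0.434 (permutation p = 0.164). Without the 2 libraries farthest from the median coverage r was 0.401 and rho 0.345. Further counts use the 35110 strongest intervals of each library unless another setting is named. Lists of equal length were not equally stringent. The cut fell at a deposited −log10 q of 1.31 in KO stimulated replicate 1, 4.60 in KO stimulated replicate 2 and 5.76 in WT control replicate 1. In the WT stimulated libraries it fell at 16.6 to 27.05, so stronger peaks were left out there.

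These gave 45082 regions with a median width of 1193 bp, of which 21089 (46.8%) were called in all 12 libraries and 91.4% lay within 50 kb of a protein-coding gene. Each library had 31101 to 34191 of them. Stimulation was the main division among the libraries. The mean Jaccard index (shared regions over regions called in either) was 0.867 within WT control, 0.886 within WT stimulated, 0.866 within KO control and 0.785 within KO stimulated cells. It was 0.674 between WT control and WT stimulated and 0.685 between KO control and KO stimulated, against 0.835 between WT and KO control and 0.786 between WT and KO stimulated cells. The KO stimulated libraries stood apart from one another: replicate 3 had an index of 0.837 to 0.840 with the WT stimulated libraries and of 0.758 and 0.821 with the other libraries of its own group, and replicate 1 had 0.732 to 0.736 with the WT stimulated libraries.

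**Figure D1:**
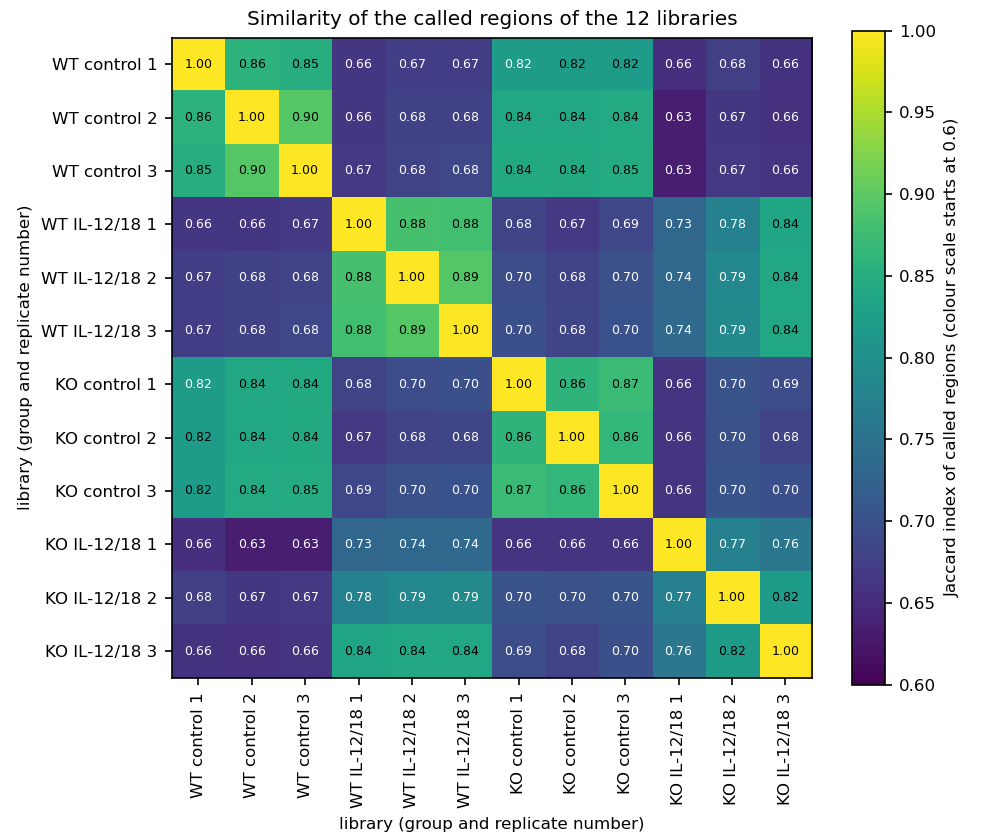
Jaccard index of called regions for every pair of the 12 libraries, both axes listing group and replicate number, with a colour scale that starts at 0.6. Control libraries of both genotypes form a block with group means of 0.835 to 0.867, and stimulated libraries share less with controls, 0.656 to 0.688 on average.

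The deleted gene was examined first. Zc3h12a lies on chromosome 4 at 125118414 to 125127881 (mm10). A peak at its upper end was in all 12 deposited lists, with folds of 62.5 to 138. In the full lists, a weak region at the lower end of the gene, 125117670 to 125118634, held a deposited peak in 6 of 6 WT libraries (folds of 2.56 to 4.33) and in 0 of 6 KO libraries (unadjusted exact p = 0.005, the smallest the 400 rearrangements can give). Which part of the gene is deleted is not known here, so this region does not check the genotype directly. Among the equal lists Zc3h12a had 8 regions, of which 6.67 ± 0.577 were called in WT control, 8 ± 0 in WT stimulated, 7.33 ± 0.577 in KO control and 8 ± 0 in KO stimulated libraries (SD, n = 3), and none passed the treatment or the genotype test.

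Stimulation with IL-12/18 changed which regions were among the strongest peaks at genes of several functions. Gzmk, which encodes a granule protease, had 0 called regions in either control group and 2.33 ± 0.577 in WT and 3.00 ± 0 in KO stimulated libraries. Il7r (the IL-7 receptor), Klrc1 (the inhibitory receptor NKG2A) and Cd274 (the checkpoint ligand PD-L1) each had 2 regions that became higher, and Zc3h12c, a relative of Regnase-1, had 3. Cd27, a receptor of less mature NK cells, had 2 lower regions: 2 ± 0 were called in each control group and 0 in each stimulated group. Tcf7, a transcription factor of early NK and T cells, had 3 regions that became lower, and so did Cd226, which encodes an activating receptor and also had 1 higher region. These are changes in peak rank, and weaker deposited peaks often remained. Both higher Gzmk regions had deposited peaks in some control libraries (in 1 and 2 of 3 for WT, 3 and 2 of 3 for KO), and the Cd27 region across the gene's upper end had them in 3 of 3 WT and 2 of 3 KO stimulated libraries, while the other Cd27 region had none there. The 3 lower Tcf7 regions each had a deposited peak in 3 of 3 WT stimulated libraries. With all deposited peaks, higher minus lower regions came to 0 at Gzmk, Il7r, Cd274, Tcf7 and Cd226, 1 at Klrc1 and Zc3h12c and −1 at Cd27. With 17555 peaks per library they came to 0 at Gzmk, Cd274, Zc3h12c, Cd27 and Cd226, 1 at Il7r and Klrc1 and −3 at Tcf7, and with calls that cover 50% of the region to 0 at Cd27.

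Across both genotypes 2985 regions were higher and 2292 lower in stimulated cells, of 8834 that could be tested (exact conditional permutation test, adjusted p = 0.0169 for the 2617 regions with a call in 6 of 6 libraries of one treatment and 0 of 6 of the other, and 0.0335 for the rest). Of the fully separated regions, 1625 were called only with stimulation and 992 only without. Of the regions gained in WT 2572 had no deposited peak of any strength in the control libraries, and of those lost 316 had none in the stimulated libraries. In WT cells 4245 regions were gained and 2896 lost, with 24403 called in all 6 libraries. In KO cells 2342 were gained and 2097 lost, with 22611 called in all 6 libraries. A region with 3 calls among 6 libraries divides 3 against 0 by chance in 10% of arrangements. With all deposited peaks 7292 were gained and 1036 lost in WT and 1411 gained in KO, and with 17555 peaks per library 2138 and 1725 in WT and 1389 and 1151 in KO. With all deposited peaks in place of equal lists the treatment test gave 1144 higher and 395 lower regions, and with 17555 peaks per library 1630 and 1381.

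**Figure D2:**
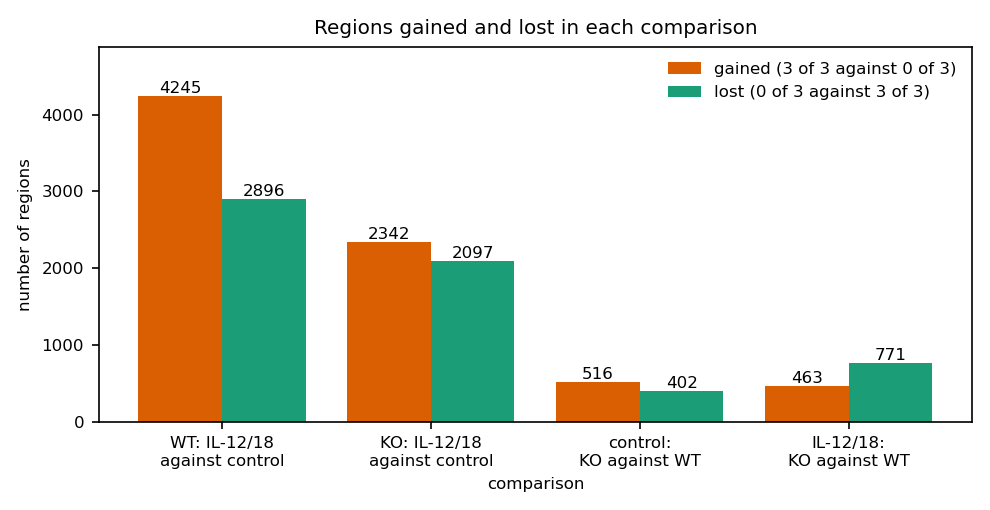
Number of regions gained (called in 3 of 3 libraries of the first group and 0 of 3 of the second) and lost (the opposite) in each of the 4 comparisons. Bars are counts without error bars: stimulation gives 4245 gained and 2896 lost regions in WT and 2342 and 2097 in KO, and genotype gives 516 and 402 in control and 463 and 771 in stimulated cells.

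The changing regions lay away from gene ends. Within 1 kb of a gene end were 4.62% of the regions gained in WT (Wilson 95% interval 4.03 to 5.29) and 13.4% of those lost (12.2 to 14.7), against 41.7% of the shared regions (41.1 to 42.3). The KO shares were 4.87%, 10.5% and 43.5%. The sets were not matched for width, and a wider region comes within 1 kb of a gene end more easily. Median widths of gained, lost and shared regions were 848, 895 and 1647 bp in WT and 956.5, 820 and 1713 bp in KO. Gained regions were inside gene bodies but away from their ends in 50.6% of cases in WT and 49.4% in KO.

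The Ifng locus, which encodes interferon gamma (chromosome 10, 118441046 to 118445894), had 16 regions within 50 kb. WT control libraries had 11 ± 1.00 of them, WT stimulated 15.7 ± 0.577, KO control 12 ± 1.00 and KO stimulated 14 ± 1.00 (SD, n = 3). The region at 118451240 to 118452598, 5.3 kb above the gene's upper end, was called in 6 of 6 stimulated and 0 of 6 control libraries (exact permutation test, adjusted p = 0.0169), and no control library had a deposited peak of any strength there. The region at 118461007 to 118461802, 15.1 kb away, was called in 3 of 3 WT and 2 of 3 KO stimulated libraries and 0 of 6 control libraries (exact permutation test, adjusted p = 0.0335). There 1 KO control library held a weaker deposited peak. The region over the gene itself was called in all 12 libraries and so counts as unchanged, although its peaks differed in width. Among the strongest peaks they ended at 118442787 to 118443834 in control libraries, inside the gene. In stimulated libraries they reached 118448517 to 118449448, beyond its upper end, in KO stimulated replicate 2 as 2 peaks. KO control replicate 3 held weaker peaks beyond that end. The balance of 2 higher and 0 lower regions at Ifng came to 6 with 17555 peaks per library, 7 with calls that cover 50% of the region, 6 with summit windows and 1 with all deposited peaks. Of the other genes fixed in advance, Pou2f2 (the octamer factor OCT2, 8 regions) and Nfkbiz (the NF-kB cofactor IkB-zeta, 7 regions) had none that changed.

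**Figure D3:**
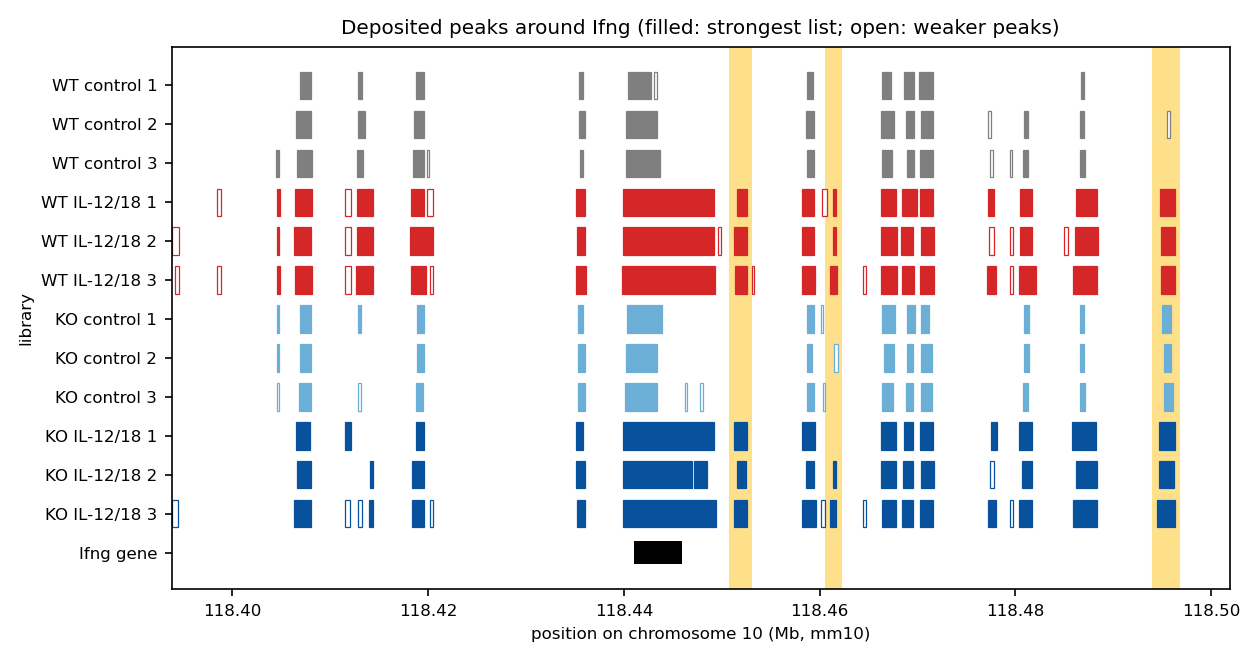
Deposited peaks of each library along chromosome 10 around Ifng, position in Mb on the horizontal axis and 1 line per library, with filled boxes for the 35110 strongest peaks, open boxes for weaker ones and the gene body in black. Shading marks the regions at 5.3 kb and 15.1 kb above the gene, called only in stimulated libraries, and a region 48.5 kb above it, called in 0 of 3 WT control libraries and in 3 of 3 libraries of each other group.

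Of 238 genes on the fixed lists, 87 had at least 1 region that changed with stimulation. Among the NF-kB pathway genes, which relay IL-18 signals, 5 of 18 had only higher regions, 2 had both and 11 had neither. Nfkb1, a precursor of the NF-kB subunit p50, had 4 higher and 2 lower regions, and Tnfaip3, the NF-kB inhibitor A20, had 2 higher. In all, 12 regions of this list were higher and 3 lower, the same numbers when adjusted over the list alone. Of 17 cytokine and chemokine genes 7 had only higher regions (Ifng and Il10 had 2 each), 3 only lower and 7 neither, with 9 higher and 3 lower regions, also when adjusted over the list alone. Of 19 genes for RNA decay and reported Regnase-1 targets 6 had only higher regions, 3 only lower, 1 both and 9 neither. Beside Zc3h12c they were Ifng, Rel, Rc3h1, Il2 and Il12b, with 10 higher and 4 lower regions in the list, again the same when adjusted over the list alone. Of 24 NK transcription factors 10 had only higher regions, 4 only lower, 2 both and 8 neither. Prdm1, which encodes the differentiation factor BLIMP1, had 3 higher regions, with 8 ± 0 called in WT control and 13.3 ± 0.577 in WT stimulated libraries. Zeb2, a factor of terminal NK maturation, had 3 higher regions, while Runx3, which NK cells need to develop, had 2 lower. Of 14 AP-1 genes 5 had only higher regions, among them Batf3 with 2, and 1 only lower, 1 both and 7 neither. Of 12 cytotoxic granule genes 2 had only higher regions (Gzmk and Serpinb9), 1 only lower (Ctsw) and 9 neither. Of 12 checkpoint genes 2 had only higher regions (Cd274 and Lag3), 1 only lower, 1 both and 8 neither.

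Counted per library, 9 of the 16 lists had more called regions in stimulated cells. The NF-kB list went from 71.0 ± 2.65 to 82.3 ± 2.52 regions in WT and from 71.0 ± 2.65 to 80.7 ± 2.08 in KO (SD, n = 3), a mean rise of 10.5 (exact permutation test, p = 0.005, the smallest possible, adjusted p = 0.016). The RNA decay list rose by 11, from 57.7 ± 0.577 to 73.0 ± 1.73 in WT and from 62.0 ± 1.00 to 68.7 ± 3.51 in KO, the cytokine list by 7, growth and metabolism by 4.33 and the ubiquitous genes by 5 (exact permutation tests, adjusted p = 0.016 each). In these 5 lists every stimulated library lay above every control library of its genotype. The AP-1 list rose by 6.83 (exact permutation test, adjusted p = 0.04), and NK transcription factors by 8.33, checkpoint genes by 3.67 and cytotoxic granule genes by 2.17 (exact permutation tests, adjusted p = 0.0444 each). For all regions near genes the difference was −600 (exact permutation p = 0.18). The ubiquitous genes, a background list, went from 36.7 ± 0.577 to 42.7 ± 0.577 regions in WT and from 36.7 ± 0.577 to 40.7 ± 1.53 in KO (SD, n = 3). Their rise of 5 thus stood on a smaller base than the rise of the NF-kB list. Their higher regions were at Ywhaz, an adaptor protein (3), and Ptprc, the leukocyte antigen CD45 (1). Ifng, Il6 and Il2 are on both the cytokine and the RNA decay list, so the rises of these 2 lists are not separate results. Fisher's exact test found no list enriched among the higher or lower regions (smallest adjusted p = 0.411). Rearranged within replicate numbers as a block no list passed, where the smallest possible exact permutation p is 0.0312 before adjustment. With all deposited peaks none of the 9 list calls held (adjusted p = 0.267 for NF-kB and 0.36 for RNA decay), with calls that cover 50% of a region 2 held (NF-kB and cytokines), without KO control replicate 2 or KO stimulated replicate 2 there were 5, and with 17555 peaks per library cytotoxic granule genes turned to −3.33 (exact permutation test, adjusted p = 0.0133). Several calls ended when a single library was left out. Fewer rearrangements then remain, which can raise p, so these endings do not by themselves show dependence on single libraries. The differences kept their sign with each library left out in turn. They were 2.67 to 5.08 for checkpoint genes, 1.5 to 2.75 for cytotoxic granule genes and 6 to 9.75 for NK transcription factors. For AP-1 they were 5.17 to 7.67, and for growth and metabolism 2.92 to 4.83. The checkpoint call ended when any of 11 of the 12 libraries was left out and the cytotoxic granule call with any of 10. The NK transcription factor call ended with any of 8, and the AP-1 call without WT control replicate 3, KO control replicate 2 or KO stimulated replicate 3. The growth and metabolism call ended without KO stimulated replicate 2 (exact permutation test, adjusted p = 0.0686) and with 17555 peaks per library (0.167), and its difference turned to −0.167 with calls that cover 50% of a region.

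**Figure D4:**
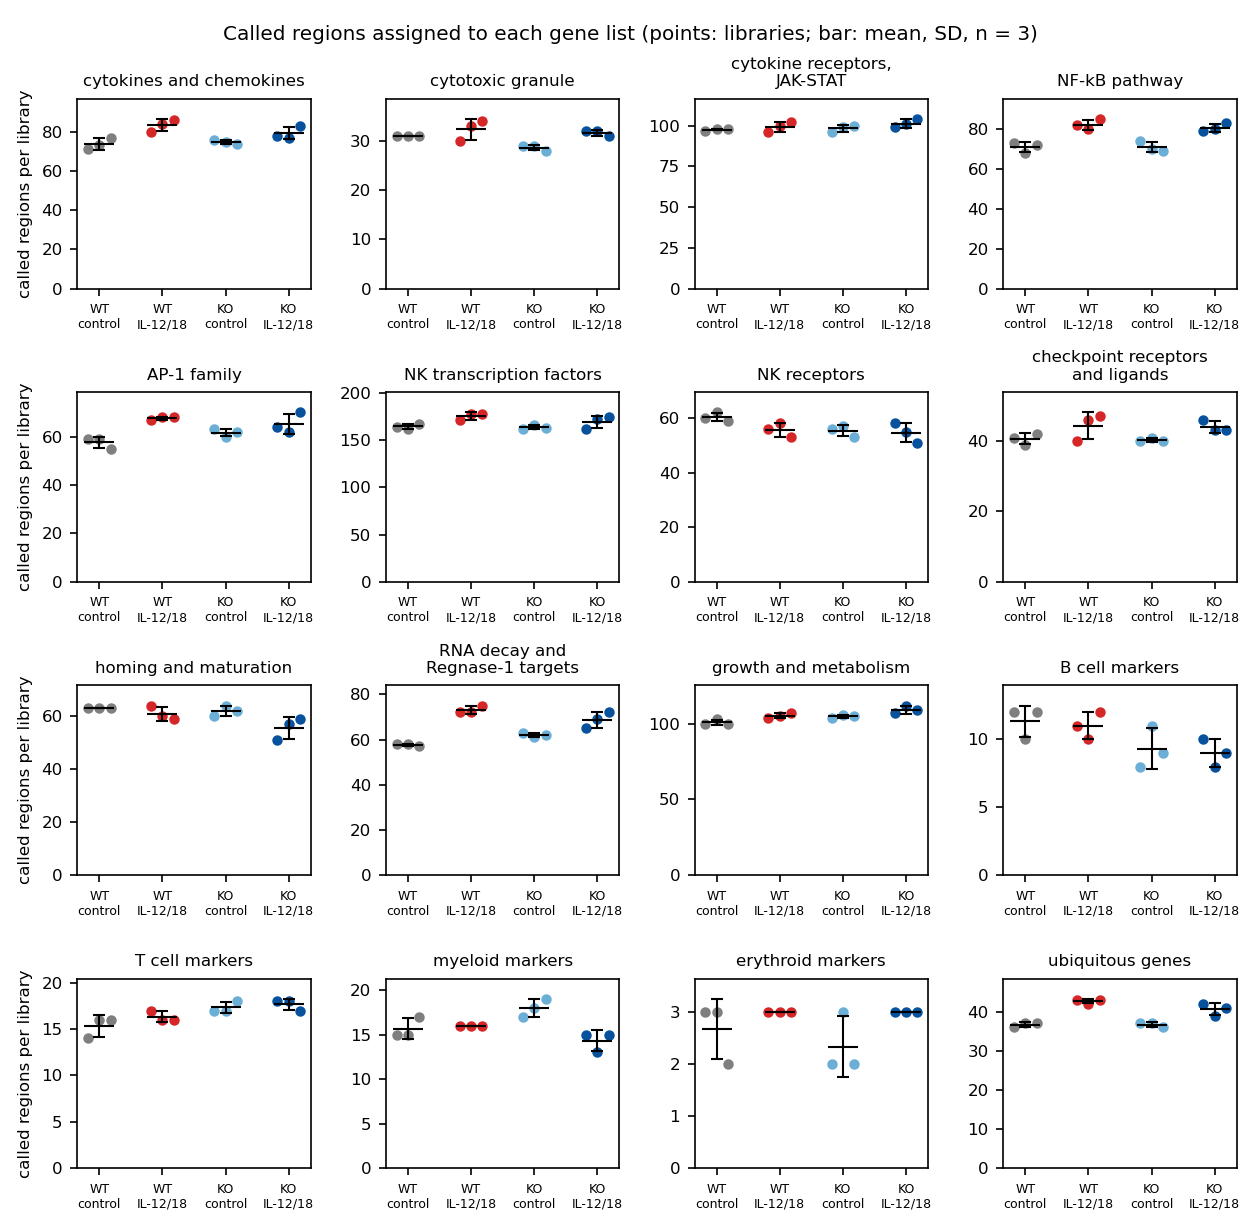
Called regions assigned to each of the 16 gene lists, per library (points) with mean and SD of the 3 libraries of each group (bars), vertical axes from 0. In the NF-kB list all stimulated libraries have 79 to 85 regions and all control libraries 68 to 74, while the marker lists of other cell types hold 2 to 19 regions in every library.

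Lists that did not pass were homing and maturation with a difference of −4.17 (exact permutation test, adjusted p = 0.056), NK receptors with −2.67 (0.172), cytokine receptors and JAK-STAT with 2.33 (0.167), and the markers of myeloid cells with −1.67 (0.167), B cells with −0.333 (0.795), T cells with 0.667 (0.341) and erythroid cells with 0.50 (0.229). Other settings moved some of these across the threshold, homing in both directions (exact permutation tests, adjusted p in brackets). Homing came to 3 with 17555 peaks per library (0.0178), −6.67 with summit windows (0.0133) and −7.17 with 20 kb flanks (0.02), and it passed without WT control replicate 3, WT stimulated replicate 1 or 2, or KO stimulated replicate 3 (0.01 to 0.0457). Cytokine receptors and JAK-STAT came to 6.17 with 17555 peaks (0.0133), 8.17 with summit windows (0.016) and 3.75 without WT stimulated replicate 1 (0.01), and NK receptors to −6.83 with summit windows (0.016). With 20 kb flanks T cell markers came to 3.83 (0.02) and B cell markers to −3.33 (0.0343), and B cell markers to −1.83 with 17555 peaks (0.0133). With longer equal lists that leave out KO stimulated replicate 1, a setting chosen after seeing the data, NK receptors came to −3.75 (0.048) and myeloid markers to −3 (0.01). Homing genes had 6 higher and 6 lower regions. Ccr7, the receptor that guides lymphocytes to lymph nodes, had 3 lower and 1 higher. Among the JAK-STAT genes Jak1 had 3 lower regions and Jak2 had 1 higher. In growth and metabolism Cdk6 had 3 higher regions, Hk2 (hexokinase 2) 2 higher and 1 lower, and Odc1, which makes polyamines, 2 lower. Over the whole genome the most higher regions were at Lpp (13 higher, 0 lower), a focal adhesion protein, Foxp1 (7 and 1), a transcription factor of lymphocyte quiescence, Atp8b4 (6 and 0) and Sox5 (6 and 0). Most lower regions were at Arid1b (5 lower, 2 higher), a chromatin remodelling subunit, Zbtb16 (4 and 0), which encodes PLZF, a factor of innate lymphocyte development, Zmiz1 (4 and 0) and Ubash3b (4 and 1). With all deposited peaks the balance turned at Arid1b and came to 0 at Zbtb16, Zmiz1, Ubash3b, Ccr7, Jak1, Odc1, Runx3, Cdk6, Hk2 and Ywhaz, so no gene named for most lower regions kept more lower than higher ones. It stayed positive at Lpp (6), Atp8b4 (5), Foxp1 (4) and Sox5 (2). With 17555 peaks per library it turned at Ccr7, Jak1 and Ubash3b, came to 0 at Zbtb16, Zmiz1, Runx3, Odc1, Batf3 and Hk2, and was −1 at Arid1b.

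Among the equal lists fewer regions were gained or lost between genotypes than between treatments. In control cells 516 regions were gained and 402 lost in KO against WT, and in stimulated cells 463 were gained and 771 lost. This ordering did not hold with all deposited peaks, where KO against WT stimulated cells gave 78 gained and 2816 lost regions, more lost than the 1036 lost in WT and the 1411 gained in KO on stimulation. The regions gained in KO included those around Batf, an AP-1 factor of activated lymphocytes, with 3.00 ± 0 called in WT control and 5.33 ± 0.577 in KO control libraries, around Bcl2, which protects from apoptosis (13.3 ± 0.577 and 16.7 ± 1.2), and around Il12rb2, the signalling chain of the IL-12 receptor (5.67 ± 0.577 and 7.67 ± 0.577; SD, n = 3). Bach2, a repressor that keeps lymphocytes in a resting state, had 3 regions lost in KO stimulated against WT stimulated cells and none gained. Lost here does not mean that a region was called before stimulation. Bach2 had 17.0 ± 1.00 called regions in WT control, 20.3 ± 0.577 in WT stimulated, 17.7 ± 1.2 in KO control and 16.7 ± 1.2 in KO stimulated libraries (SD, n = 3). On stimulation it gained 5 regions in WT and 1 in KO cells. None of the regions gained or lost between genotypes passed the adjusted genotype test.

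Of 1817 regions that could be tested for genotype in both treatments, the exact conditional permutation test called 0 after adjustment, the same count as Fisher's exact test without strata gave. An exact sign test within replicate numbers, where only 89 regions are testable, called 57, the fully separated ones (adjusted p = 0.0488). That equal numbers form pairs is not established. At an unadjusted p under 0.05 there were 248 regions (135 higher and 113 lower in KO), and 57 were fully separated, 31 called in 6 of 6 KO and 0 of 6 WT libraries and 26 the opposite. The smallest adjusted p was 0.147, and 182 fully separated regions would have been needed for any to pass. A region in Bcl2 at chromosome 1, 106569000 to 106570847, and one 19.1 kb above Il12rb2 at chromosome 6, 67395428 to 67396433, were among the 31 (exact p = 0.005 each, adjusted p = 0.147). The full lists held weaker peaks in all 3 WT stimulated libraries at the Bcl2 region and in 2 of 3 at the Il12rb2 region, and in 0 of 3 WT control libraries at both.

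Of the list genes 49 had a region gained or lost between genotypes in at least 1 treatment. Cdk6, Zeb2 and Batf had 3 gained and 0 lost each, Bcl2, Il12rb2 and Stat4 (a transducer of IL-12 signals) 2 and 0, and Ikzf2 1 and 0. Ifng, Jak2 and Prdm1 had 1 gained and 1 lost each. Bach2 had 3 lost, Ets1 2, and Runx1, Ebf1, Ptprc and Itga2 1 each. Over the genome the most gained were at Ece1 (4 gained, 0 lost), Inpp4b (4 and 1), a lipid phosphatase, and the predicted genes Gm10354 (6 and 0) and Gm17019 (4 and 0). The last pair lie close together on chromosome 5 in a family of near-identical copies, where reads cannot be placed with certainty. Most lost were at Ank3 (5 lost), Galnt10 (4), Trio (3) and Zmat4 (3). The net balance for Bcl2 turned to −1 with all deposited peaks and with 17555 peaks per library, and with all deposited peaks it came to 0 at Cdk6, Inpp4b and Gm10354. With 17555 peaks per library it came to 0 at Cdk6, Batf, Bach2, Il12rb2, Ets1, Stat4, Ebf1, Ptprc, Itga2, Gm10354, Gm17019, Inpp4b, Ank3 and Zmat4.

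No gene list differed by genotype after adjustment over the 16 lists. Growth and metabolism had 4 more regions in KO (exact permutation p = 0.01, adjusted p = 0.08) and T cell markers 1.67 more (p = 0.01, adjusted p = 0.08), while B cell markers had −2 (p = 0.03, adjusted p = 0.16, exact permutation tests). The remaining lists had adjusted p-values of 0.267 to 1, myeloid markers with 0.333 (exact permutation p = 0.845). The counts between genotypes can be expected to rise when a library is left out, since the rule of 3 of 3 against 0 of 3 is then looser. The following rises therefore do not by themselves show that the counts depend on single libraries. Without KO stimulated replicate 3, 1086 regions were gained and 1964 lost between stimulated cells, and 791 and 756 were gained without KO stimulated replicates 1 and 2. Between control cells 784, 616 and 689 regions were lost without WT control replicates 1, 2 and 3, and 662 and 616 without KO control replicates 2 and 3. Only 120 of the 516 regions gained in KO control cells and 21 of the 463 gained in KO stimulated cells had no deposited peak of any strength in the WT libraries.

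The responses of both genotypes to stimulation overlapped. Of the 4245 regions gained in WT and the 2342 gained in KO, 1625 were gained in both (38.3% of the WT and 69.4% of the KO regions), and 1 was lost in KO. Of the lost regions 992 were shared, and 0 went the opposite way. Lists independent over all 45082 regions would share 220 gained and 135 lost regions. That base includes 21089 regions called in all 12 libraries, which cannot be gained or lost, so these expectations are too low. No libraries are shared between these contrasts. Of the regions gained in WT, 2267 were called in 3 of 3 KO stimulated libraries and 376 in none. Prdm1 had 4 regions gained in WT and 2 in KO, and Zeb2 3 and 4. By the difference of differences no gene list responded differently after adjustment. The RNA decay list gave −8.67 regions, KO minus WT (exact permutation p = 0.015, adjusted p = 0.12), and myeloid markers gave −4 (p = 0.01, adjusted p = 0.12, exact permutation tests). Without KO stimulated replicate 3, the library of its group closest to WT stimulated cells, 2 lists passed, among them RNA decay with −10.5 (exact permutation p = 0.005, adjusted p = 0.04).

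Some regions gained with stimulation in WT cells were already called in unstimulated KO cells. There were 252 regions called in 0 of 3 WT control, 3 of 3 WT stimulated and 3 of 3 KO control libraries, of which 228 were also called in 3 of 3 KO stimulated libraries. The opposite pattern, with the genotypes exchanged, had 37 regions. On the fixed lists the 252 included regions at Ifng (chromosome 10, 118494426 to 118496340), Il10 (chromosome 1, 131037962 to 131038589), Xcl1, Il6, Ctla4, Bcl2, Pim1, Cdk6, Jak2, Il12rb2, Nfil3, Zeb2 (chromosome 2, 44955917 to 44958080) and Zc3h12a itself, 17.3 kb from the gene, and at the markers Cd6 and Adgre1. Of the 252 regions 51 had no deposited peak of any strength in the WT control libraries, among them those at Il10 and Zeb2. The regions at Ctla4, Xcl1, Adgre1, Zc3h12a and Cdk6 had a weaker deposited peak in 3 of 3 WT control libraries, those at Bcl2, Nfil3 and Il12rb2 in 2 of 3, and those at Ifng, Il6, Pim1, Jak2 and Cd6 in 1 of 3. Of regions selected without the measured library, 6.74% ± 2.19 were called in the left-out WT control library and 14.6% ± 1.78 in KO control libraries (SD, n = 3), a difference of 7.90 percentage points (exact permutation p = 0.1, the smallest possible with 3 against 3, so this design cannot reach 0.05). With calls that cover 50% of the region the difference was 2.92 points (exact permutation p = 0.4).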

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

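The tests of the WT-gained regions in KO control cells and of the fewer gained regions, and those that leave out KO stimulated replicate 1, were chosen only after the result was seen, while the random gene lists and the other splits of the libraries were planned.

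A difference between the genotypes in their response to stimulation brought up 2 gene lists, each with an unadjusted p under 0.05 by the difference of differences and an adjusted p above it. The RNA decay list, which holds Regnase-1 relatives and reported target messages, gave −8.67 regions (exact permutation p = 0.015, adjusted p = 0.12). By gene the largest parts were at Ifng with −2.67 and Rel, an NF-kB subunit, with −1.67. Myeloid markers gave −4 (exact permutation p = 0.01, adjusted p = 0.12), and 0 with the longer equal lists that leave out KO stimulated replicate 1.

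The smaller rise of the RNA decay list in KO cells was weighed against 2 technical explanations. The short list of KO stimulated replicate 1 as the whole cause is argued against, since the difference was −7.83 without it. A property of any list with as many regions stays open: among 10000 random gene lists matched on regions per gene the median was −2.67 (SD 3.51), and the real value lay at percentile 5.4, inside the central 95%. The values are consistent with a weaker response over many genes, of which this list need not be special. With 17555 peaks per library the difference was −2 (exact permutation p = 0.55), and without KO stimulated replicate 3 it was −10.5 (adjusted p = 0.04).

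Regions gained by stimulation in WT cells were called more often in KO control than in left-out WT control libraries, by 7.90 percentage points. The log2 ratio of KO to WT share was higher by 0.73 (SD 0.30) for regions called in 3 of 3 WT stimulated libraries than in 2 of 3. This stands against KO control lists holding more of any weak region as the whole cause. As a part of it that stays open, since the KO share was also the higher one for the 2 of 3 regions (log2 ratios 0.43, 0.69 and 0.21). The 3 differences share libraries, so their SD does not measure independent samples. Against a bias of the left-out design as the whole cause stands the exchanged comparison, with −1.41 points (pooled SD 1.77). A smaller bias of this kind stays open as a part of it, since a genotype difference would work against it in the exchanged comparison. Depth stays open, since the implied background coverage of KO control minus WT control libraries was −0.114, within the spread of 0.635. An effect of the genotype also stays open and was not tested apart from these.

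Fewer regions were gained on stimulation in KO than in WT cells, 2342 against 4245 (1411 against 7292 with all deposited peaks and 1389 against 2138 with 17555 peaks per library). Against the short list of KO stimulated replicate 1 as the whole cause stands a count of 3231 without it, below the 4686 to 4710 gained in WT with 1 stimulated library left out (SD of the matching KO counts 212). Against regions already called in KO control cells as the whole cause stand 843 WT-gained regions called in at least 1 KO control library, fewer than the deficit of 1903. Lower depth of the KO stimulated libraries stays open, with a coverage difference of −0.732 and a spread of 0.938. Of the WT-gained regions 1419 were called in 0 KO control and 1 or 2 KO stimulated libraries, missing the 3 of 3 rule. The KO stimulated libraries were less alike than the WT stimulated ones (mean Jaccard index 0.785 and 0.886). Differences among the KO stimulated libraries thus stay open as well. An effect of the genotype cannot be told apart from these or from depth, since total depth is unknown and the coverage spread exceeds the coverage difference.

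Other splits of the libraries were counted for each comparison of regions. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and in each comparison 1 of 10 splits, the real one, gave as many gained and lost regions. The real and highest other counts were 7141 and 125 for stimulation in WT, 4439 and 210 in KO, 918 and 212 for genotype in control cells, and 1234 and 217 in stimulated cells. Over both genotypes 1 of 100 drawn splits, the real one, gave as many stimulation regions, with 5277 against at most 0 in the others. At least 884 regions must pass together for any to pass the adjustment, so a count of 0 does not tell how far the other splits fell short. Over both treatments 1 of 100 drawn splits gave as many genotype regions at an unadjusted p under 0.05 (248 against at most 103), and 1 of 100 as many fully separated regions (57 against at most 5). The labels' grouping by genotype thus stood out among the drawn splits, although no single genotype region passed the adjusted test within strata. Such splits treat the libraries as independent samples. The labels do not say whether the 3 libraries of a group came from separate animals, so a source shared within a group cannot be told apart from the genotype.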

How the results depend on the processing

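Chosen only after the data were seen were the longer equal lists, the demand for no deposited peak of any strength in the other group, and the settings tried for single genes, for the comparison of both responses and, beyond the planned 2, for the WT-gained regions in KO control. Counts were labelled the same within 1.5 times, also where both were 0, and balances at single genes within 1 region. Tested differences were labelled the same when their sign and their side of the threshold held, whatever their size. Of the results that answer a comparison, 314 values were the same by these rules, 52 moved and 1 reversed. Of the other values 1526 were the same, 113 moved, 65 fell short of the threshold, 16 newly passed it and 40 reversed. The cause was not tested unless stated. With all deposited peaks, regions gained and lost were 7292 and 1036 for stimulation in WT, 1411 gained in KO, and 78 and 2816 for KO against WT stimulated. The treatment test gave 1144 higher and 395 lower regions (2904 and 1275 at an unadjusted p under 0.05), 395 were lost in both genotypes and 0 gene lists passed. Genotype differences turned to −8.17 for cytokine receptors and JAK-STAT, −6.67 for AP-1, −17.5 for growth, −1.33 for T cell markers and −2.67 for myeloid markers, and the balance of regions to 1 at Arid1b (stimulation) and −1 at Zc3h12a and Bcl2 (genotype). With 17555 peaks per library counts fell by construction, to 2138 and 1725 in WT, 1389 and 1151 in KO, 226 and 253 for genotype in control and 228 and 316 in stimulated cells, 1630 higher and 1381 lower regions, and 1001 gained in both. Treatment differences turned to −3.33 for cytotoxic granule, 0.667 for NK receptors and 3.00 for homing, genotype differences to −1.83 for cytokine receptors, −1.67 for AP-1, 1.33 for NK transcription factors, 0.833 for checkpoint genes and −0.667 for growth, and the balance to 1 at Ccr7, 2 at Jak1 and 1 at Ubash3b (stimulation) and −1 at Bcl2 and 1 at Runx1 (genotype). With calls that cover 50% of the region 681 regions were lost between genotypes in control and 1597 in stimulated cells, 2 lists passed for treatment, and the difference in WT-gained regions in KO control was 2.92 points (exact permutation p = 0.4). Treatment differences turned to −0.167 for growth and −1.50 for T cell markers, and genotype differences to −7.33 for cytokine receptors, −4.17 for AP-1, −5.83 for growth, −0.833 for T cell and −0.667 for myeloid markers. Under summit windows the AP-1 list no longer passed for treatment (exact permutation test, adjusted p = 0.0615) and cytokine receptors, NK receptors and homing did, and under 20 kb flanks AP-1, NK transcription factors, cytotoxic granule and ubiquitous genes no longer passed and homing, T cell and B cell markers did. Summit windows turned the genotype differences of cytokine receptors to −0.833 and of AP-1 to −1.17, and 20 kb flanks turned myeloid markers to 0.167 for treatment and −0.833 for genotype. Rearranging within replicate numbers as a block gave 1625 higher and 992 lower stimulation regions, 31 and 26 genotype regions, and 0 lists, whose smallest possible p is 0.0312 over 64 sign patterns. The genotype regions pass there because only 89 regions are testable, of which the exact permutation test calls 57 (adjusted p = 0.0488). Correlations taken to look for pairing covered only libraries of different groups. They do not describe the similarity of whole libraries, whose mean Jaccard index between groups was 0.656 to 0.835. For the same number they ran from −0.0254 to 0.0734 (mean 0.0151). For different numbers they ran from −0.0692 to 0.0454 (mean −0.00751). The same-number mean was slightly higher while the ranges overlapped, so a weak pairing by number stays possible. Longer equal lists without KO stimulated replicate 1 gave 974 and 1432 regions for KO against WT stimulated, and turned genotype differences to −2 for growth and −0.667 for myeloid markers and Runx1 to 2 (stimulation). With no deposited peak of any strength in the other group, a stricter demand by construction, 2572 and 316 regions remained in WT, 968 and 856 in KO, 120 and 40 for genotype in control and 21 and 278 in stimulated cells. Leaving out a library loosens the rule of 3 of 3 against 0 of 3, so counts of gained and lost regions can be expected to rise by construction. Each library left out in turn gave 402 to 784 regions lost between genotypes in control cells (784, 616 and 689 without WT control replicates 1, 2 and 3, 662 and 616 without KO control replicates 2 and 3). In stimulated cells 463 to 1086 were gained and 771 to 1964 lost (791, 756 and 1086 gained without KO stimulated replicates 1, 2 and 3). Leaving out single libraries gave 5 to 11 lists for treatment, 5 of them without KO control replicate 2 or KO stimulated replicate 2. It also gave 0 to 2 lists that responded differently, 2 of them, with RNA decay among them, without KO stimulated replicate 3. WT-gained regions in KO control ranged from 5.43 points (without WT control replicate 2, exact permutation p = 0.3) to 9.24, list length from −971 to 3827 for stimulated minus control, B cell markers from −0.667 to 0.0833 for treatment, genotype differences from −1.33 to 0.583 for checkpoint genes and −0.833 to 1.67 for AP-1, and Runx1 from −1 to 1 (stimulation). Fisher's exact test without strata and autosomes alone changed none of the counts by over 1.5 times. Peaks with −log10 q of at least 5 gave differences in list length of 841 for treatment and −7116 for genotype. The motif alternatives were not run. Depth limits all of this: total depth is unknown, and the implied coverage ran from 1.80 to 4.36.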

Other observations

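The regions named here were chosen only after the values were seen. Among the 31 regions called in 6 of 6 KO and 0 of 6 WT libraries were several at genes of immune signalling outside the fixed lists. They were picked by gene function, while most of the 31 lay elsewhere, and no enrichment was tested. One lay in Irak3 (chromosome 10, 120190562 to 120192471), which encodes an inhibitor of signalling by the IL-1 receptor family, and one in Otulin (chromosome 15, 27600612 to 27601545), a deubiquitinase that restrains NF-kB. Others were 1.0 kb from Rhoh, a GTPase of blood cells, and 28.5 kb from Cd40lg, the CD40 ligand. Among the 26 regions called only in WT libraries were one in Clec2g (chromosome 6, 128962584 to 128963532), a C-type lectin gene in the NK gene complex, one 0.3 kb from Mxd1, which opposes MYC, and one in Epsti1, an interferon-induced gene. Each had an unadjusted exact permutation p = 0.005 and an adjusted p = 0.147. Whether the other genotype held weaker deposited peaks at these regions was not examined, so they may be changes in peak rank only.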
